A study of Mus musculus with 12 samples.

How the data were processed

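Mouse cells were profiled on 12 Illumina bead arrays: PtC+ and PtC- cells (binding phosphatidylcholine or not) of TCL1-192 peritoneum and spleen with 2 arrays per group, and of wild type and young TCL1 peritoneum with 1 array per group. Per the labels, RNA was extracted with Trizol and cleaned on RNeasy columns with DNase, and biotinylated cRNA was made with the Ambion MessageAmp kit. Sorting gates, donor animals, array chips and export software are not given in the sources used here, nor is the meaning of 192 in the name TCL1-192.

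The deposited non-normalized table held a signal intensity (average bead signal) for 45281 probes on each array, linear and never below 0 per the values. Per the file headers it also held a detection p-value for each probe against the negative controls of its array. The authors' second deposited table held intensity values that had the same quantiles on every array (medians of 119.2 to 119.3), so they were quantile normalized on a linear scale; its tool is not given in the sources used here. On a log scale each of its columns correlated most closely with the same array of the first table (r of 0.991 to 1).

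Calculations started from the non-normalized signals in R 4.3.3 with limma 3.58.1. The function neqc corrected background with control values inferred from the detection p-values, added an offset of 16, quantile normalized and took log2. Probes were kept where the detection p-value was under 0.05 on at least 2 arrays (18100 probes), and for each symbol the kept probe with the highest mean was used (3479 symbols had several), leaving 13190 genes. Of these symbols 8112 were in the RefSeq table, 2579 matched 1 of its synonyms and 2499 neither, so symbols are given as on the array, with the current one where it differs. No genome build was used. The array with raised background is the PtC- peritoneal TCL1-192 array of replicate 2, where undetected probes had a mean signal of 205.4 against 93.12 to 114 on the others. The residual SD of its group was 0.386 against 0.151 to 0.212 in the other TCL1-192 groups.

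A linear model with 1 mean per group (8 groups, 4 residual degrees of freedom) was fitted by limma to all 12 arrays, with empirical Bayes moderation (3.13 prior degrees of freedom, prior SD 0.244). Its 9 contrasts were PtC+ minus PtC- in TCL1-192 cells over both tissues, in each tissue, and between the tissues; spleen minus peritoneum; TCL1-192 minus wild type, young TCL1 minus wild type and TCL1-192 minus young TCL1 in the peritoneum; and PtC+ minus PtC- averaged over wild type, young TCL1 and both TCL1-192 tissues. Tests were two-sided, with Benjamini-Hochberg adjustment over genes within a contrast and a threshold of 0.05. Errors given with ± are standard errors (SE) of the log2 difference from this model, and their median over genes was 0.156 to 0.359 between contrasts. Where a gene was undetected on every array of a side, the fold is a lower bound, computed with that side at the lowest detected value of each array. A pair of single arrays (wild type, young TCL1) has no test, and medians of lists there were set against 10000 random lists matched on signal in 20 bins.

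Before the data were examined, 28 gene lists were fixed, 19 of pathways and 9 of markers for other cell types. Pathway lists were B cell receptor signalling components, its negative regulators, activation genes it induces, NF-kB targets, cell cycle and proliferation, MYC targets and ribosome biogenesis, interferon-stimulated genes, MHC class II and antigen presentation, B-1 cell markers, follicular and marginal zone markers, plasma cell differentiation and secretory pathway, homing receptors and adhesion, apoptosis and survival, glycolysis and hypoxia, oxidative phosphorylation, cholesterol and fatty acid synthesis, stress and dissociation, immunoglobulin genes and cytosolic ribosomal proteins. Cell type lists were macrophage, T cell, NK cell, neutrophil and myeloid progenitor, erythroid, mast cell and basophil, mesothelial and stromal, dendritic cell, and platelet and megakaryocyte markers. Each was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 28 lists of a contrast. After list results had been seen, a fault in matching older gene symbols was corrected, which took 1 wrong gene each out of 5 lists (activation, MYC, interferon, oxidative phosphorylation, mast cell).

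Named genes followed a rule fixed before the data were examined: the 10 largest rises and 10 largest falls past the threshold (5 each in supporting comparisons) where every array of a side lay beyond every array of the other within PtC class and tissue, and up to 4 called members of each list. Where fewer than 5 genes passed, the highest moderated t was used, and gene models without a name were not named. Levels of IGKV9-128, Igh-V11, IGHV12S1, Igh-VS107, Ly6a and H2-Ea on single arrays, and the 4 immunoglobulin genes that rose, were picked out after their values were seen. The values of 1 gene that the rule names are not reported here.

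The steps were tested on simulated data with 200 changed genes in each of 5 runs. Of genes with a log2 difference of 2, 90.8% were recovered for PtC, 90% between tissues, 82.8% against wild type and 72% for young TCL1. The largest share of false calls was 10.4%, and 1 of 5 runs with no change made a call. A shifted list was found by camera in 5 of 5 runs and 0 unchanged lists were called. Simulated genes were drawn independently of one another, so this cannot show how camera behaves on lists of correlated genes. Each run mixed log2 differences of 0.5 to 4 and gave every array the same spread. Recovery may be lower in the real data, where fewer genes may change strongly and the spread of groups differed. Alternatives were fixed beforehand except array quality weights. They were quantile normalization alone, median centring, the deposited normalized values, and no filter or a stricter one (detection p-value under 0.01 on at least 6 arrays). Others were all probes, an intensity trend in the prior and blocks for replicate number and source pair. The compared arrays alone, a 2-fold minimum and leaving out each array were also used. Leaving out a lone wild type or young TCL1 array emptied its group. A comparison between donors then kept only the other PtC class, and the average over sources dropped that pair.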

Results

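Gene expression was measured on 12 Illumina mouse arrays in cells that the labels call chronic lymphocytic leukaemia (CLL) cells, sorted by whether they bound phosphatidylcholine (PtC), a self antigen recognised by many B-1 B cells. TCL1 is an oncogene whose expression in B cells gives mice a disease like CLL. TCL1-192 cells made 4 groups of 2 arrays each, PtC+ and PtC- cells from the peritoneum and from the spleen. Wild type and young TCL1 peritoneal cells gave 1 PtC+ and 1 PtC- array each, so these 4 groups had no replicates, and their lone arrays were assumed to vary like the TCL1-192 groups. The PtC- peritoneal TCL1-192 array of replicate 2 detected 10711 of 45281 probes, with a median signal of 219.2. The other arrays detected 13825 to 15192, at median signals of 99.4 to 121.4. Tests covered 13190 genes. The number of arrays limits the precision, and p-values measure the spread between replicate TCL1-192 arrays, which may be technical. For a gene undetected on those arrays, its own part of that spread is noise near the detection limit. The first principal component (45.1% of the variance) set the TCL1-192 arrays at 17.21 to 41.64 apart from the wild type and young TCL1 arrays at -76.46 to -49.1. The 6 probes for mouse Tcl1 and Tcl1b were undetected on every array, at log2 values of 4.56 to 5.18. Whether these mouse probes can report the TCL1 of the TCL1 cells is not given, so this does not show that it was absent.

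Whether PtC binding goes with a distinct expression state was asked in TCL1-192 cells, 4 PtC+ arrays against 4 PtC- arrays over both tissues. No single gene passed the test. Tyms, which encodes the thymidylate synthase needed for DNA synthesis, had the highest moderated t among higher genes, at 0.79 ± 0.12 log2 units (SE, limma adjusted p = 0.58). Mxd3, a MAX dimerization protein, differed by 0.99 ± 0.16 and the microtubule regulator Stmn1 (detected on 3 of 4 PtC- arrays) by 0.88 ± 0.16, with the same adjusted p. On the lower side, Igh-V11 differed by -0.68 ± 0.15, averaging 14.12 in PtC+ and 14.8 in PtC- cells. It is a heavy chain variable gene of a family known from PtC-binding receptors. These values lie near the array ceiling of 15.48, so the size of its difference is uncertain. Igh-VS107, from a family known from antibodies to phosphorylcholine, differed by -0.73 ± 0.19. The secretin gene Sct differed by -0.82 ± 0.15 and Tapbp, which loads peptides onto MHC class I, by -0.87 ± 0.2, none of them past the test. On the single wild type and young TCL1 pairs, without a test, Igh-V11 was instead higher in PtC+ cells (0.78 and 0.89). The heavy chain gene IGHV12S1 was higher there too (1.67 and 1.64), against -0.65 and -0.64 in TCL1-192 peritoneum and spleen. Igh-VS107 was lower in both pairs (-0.54 and -1.55).

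Cell cycle genes as a group were slightly higher in PtC+ TCL1-192 cells, with a median log2 difference of 0.3 and 33 of 34 members above 0. Of these members 0 passed over all genes and 3 passed when adjusted over the list alone. The list passed camera at adjusted p = 8.3e-09 with the preset correlation, against adjusted p = 0.8 with an estimated correlation. In the spleen alone the same list had a median of 0.4, at adjusted p = 1.2e-15 preset and adjusted p = 0.87 with an estimated correlation. In the peritoneum alone it did not pass (median 0.14, 24 of 34 above 0, adjusted p = 0.12 preset, adjusted p = 0.88 with an estimated correlation). B cell receptor signalling components (median -0.18, adjusted p = 0.011), MHC class II and antigen presentation (median -0.13, adjusted p = 0.03) and oxidative phosphorylation (median 0.11, adjusted p = 0.031) also passed with the preset correlation, each at adjusted p = 0.8 with an estimated correlation and 0 members past over all genes. When adjusted over the list alone 2 MHC class II genes were lower. With normexp and median centring, the receptor component median was 0.09 (adjusted p = 0.7) and the MHC class II median turned to 0.22 (adjusted p = 0.83). The receptor component call ended without PtC- peritoneum replicate 1 (adjusted p = 0.29) and without PtC+ peritoneum replicate 2 (0.053). The MHC class II call ended without PtC- peritoneum replicate 1 (adjusted p = 0.29), PtC- spleen replicate 1 (0.14), PtC+ peritoneum replicate 2 (0.053) or PtC+ spleen replicate 2 (0.22). The oxidative phosphorylation call ended without PtC- peritoneum replicate 1 (adjusted p = 0.78), PtC- spleen replicate 1 (0.063), PtC+ peritoneum replicate 2 (0.13), PtC+ spleen replicate 2 (0.13) or PtC- spleen replicate 2 (0.053).

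By limma 0 of 13190 genes passed adjusted p 0.05 for PtC, while 1129 had an unadjusted p under 0.05 and 660 would by chance. Without PtC- peritoneum replicate 1, which leaves the array with raised background alone in its group, 1528 genes passed. In the peritoneum alone limma gave 0 genes (2552 unadjusted), against 143 (50 higher, 93 lower) with an intensity trend in the prior and 2752 without PtC- peritoneum replicate 1. Tyms led there at 1.32 ± 0.18 log2 units (adjusted p = 0.18). In the spleen alone limma gave 0 genes (338 unadjusted). The histone gene Hist2h2ab differed there by 1.07 ± 0.17 and the polycomb gene Bmi1 by -1.2 ± 0.22 (adjusted p = 1). The test of whether the PtC difference itself differs between tissues also gave 0 genes by limma (1520 unadjusted, and 1644 passed without PtC- peritoneum replicate 1). By moderated t Polr3g, an RNA polymerase III subunit, led the falls at -1.74 ± 0.27 and Pou2f1, a transcription factor gene, the rises at 1.45 ± 0.23 (adjusted p = 0.41). Of 250 simulated genes given a log2 difference of 1, 40.4% were recovered in the comparison over both tissues. At a difference of 2 the share was 90.8%. Each simulated run also held larger changes, which ease the adjusted threshold, and gave every array the same spread. With 0 genes called and a more variable PtC- peritoneal group, recovery in the real comparison may be lower.

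The series sets out to compare CLL cells from spleen and peritoneum and here had 4 TCL1-192 arrays against 4. Splenic cells held far more mRNA of immediate-early genes, which B cell receptor signals and other stimuli switch on. Egr1, a zinc-finger transcription factor, averaged 13.79 in spleen and 7.52 in peritoneum, a 77.1-fold rise (6.27 ± 0.21 log2 units, SE, limma adjusted p = 2.1e-05). The AP-1 subunit genes Fosb and Fos rose at least 62.1-fold (Fosb was undetected on all 4 peritoneal arrays) and 28.8-fold. Atf3, a stress-induced transcription factor, rose 40.1-fold, Egr2 at least 16.4-fold, and the phosphatase genes Dusp2 and Dusp1 rose 20-fold and 18.6-fold. Also among the largest rises were Myd116, now Ppp1r15a (26-fold), the kinase gene Plk2 (14-fold) and the sulfate transporter gene Slc13a4 (13.4-fold). Atf3, Dusp2 and Myd116 were detected on 3 and Slc13a4 on 2 of the 4 peritoneal arrays, with the measured values used throughout. Of 25 tested genes in the fixed list induced by B cell receptor activation, 18 rose and 0 fell (18 and 1 when adjusted over the list alone), with a median of 1.64, or 1.46 with undetected values set to the detection limit. The list passed camera at adjusted p = 2e-08 with the preset correlation, against adjusted p = 0.35 with an estimated correlation.

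**Figure D1:**
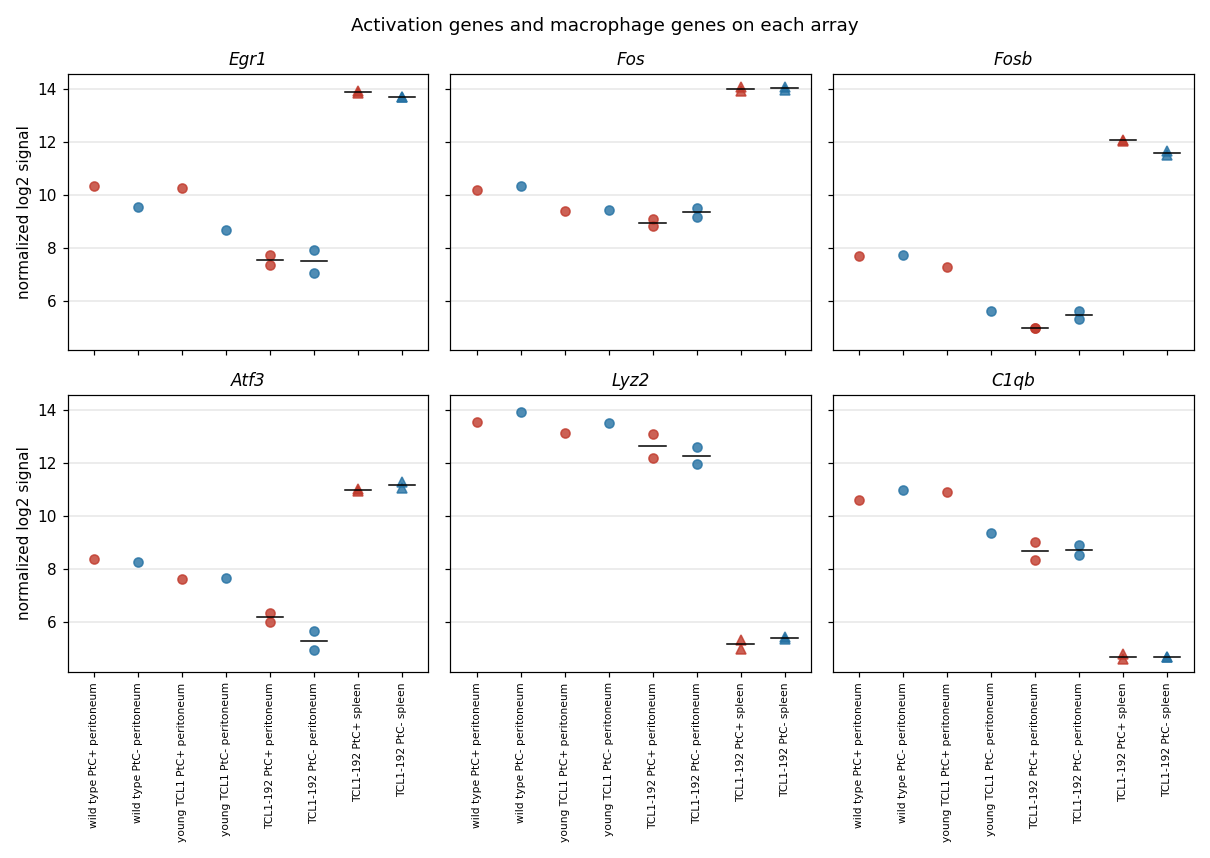
Normalized log2 signal of 4 activation genes and 2 macrophage genes, 1 point per array (red PtC+, blue PtC-, circles peritoneum, triangles spleen, bars the mean of 2 arrays). The spleen arrays are highest for Egr1, Fos, Fosb and Atf3 and lowest for Lyz2 and C1qb.

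Markers of macrophages moved the other way, beside the activation genes. Lyz2, the lysozyme gene of macrophages, fell at least 120-fold in spleen, and its second entry Lyzs at least 55-fold. Lyz (now Lyz1) fell 183-fold, while the entry under Lyz1 itself, undetected in spleen, fell at least 14.7-fold. The acute-phase gene Saa3, detected on 2 of 4 spleen arrays, fell 104-fold. Arg1, the arginase of alternatively activated macrophages, fell at least 18.5-fold, the chemokine gene Ccl9 at least 20.1-fold and the ficolin gene Fcna at least 19.2-fold. Of 19 macrophage markers 11 fell and 0 rose (12 fell when adjusted over the list alone). Their median was -1.64, or -1.08 with undetected values set to the detection limit, and the complement genes C1qb and C1qc fell at least 8.93-fold and 8.66-fold. The list passed camera at adjusted p = 3.4e-07 preset, with adjusted p = 0.4 with an estimated correlation. Erythroid markers fell as well, 5 of 8 over all genes and when adjusted over the list alone (median -1.15, or -0.63 at the limit, adjusted p = 0.00055 preset, adjusted p = 0.4 with an estimated correlation). Among them Hbb-b1, a beta globin gene, fell 24.9-fold.

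Genes of glycolysis and the hypoxia response were lower in splenic TCL1-192 cells, 11 of 23 falling and 0 rising, the same when adjusted over the list alone (median -0.63, camera adjusted p = 0.00012 preset, adjusted p = 0.44 with an estimated correlation). Ddit4, a hypoxia-induced inhibitor of mTORC1, changed by -2.33 ± 0.18 and Pdk1, which inhibits pyruvate dehydrogenase, by -2.09 ± 0.14. Of 27 MYC targets and ribosome biogenesis genes 12 fell and 1 rose (13 and 1 when adjusted over the list alone), with a median of -0.41 (adjusted p = 0.00013 preset, adjusted p = 0.44 with an estimated correlation). Rcl1, an rRNA processing gene, changed by -1.32 ± 0.13. Cytosolic ribosomal protein genes had a median of -0.25, or -0.23 at the limit, with 15 of 64 falling and 1 rising, also when adjusted over the list alone (adjusted p = 4e-04 preset, adjusted p = 0.21 with an estimated correlation). Cell cycle genes rose in 9 of 34 members and fell in 0 (10 and 0 when adjusted over the list alone, median 0.4, adjusted p = 0.00012 preset, adjusted p = 0.63 with an estimated correlation). The proliferation marker Mki67 led them at 2.27 ± 0.22. B-1 markers rose in 10 of 22 and fell in 1 (12 and 1 when adjusted over the list alone, median 0.59, adjusted p = 0.005 preset, adjusted p = 0.48 with an estimated correlation), among them Ahnak at 2.15 ± 0.24 and the inhibitory receptor gene Ctla4 at 2.09 ± 0.2 (detected on 3 of 4 peritoneal arrays). Interferon-stimulated genes rose in 10 of 28 and fell in 2 (11 and 2 when adjusted over the list alone, median 0.41, or 0.3 at the limit, adjusted p = 0.021 preset, adjusted p = 0.48 with an estimated correlation), with the ISG15 protease gene Usp18 at 1.84 ± 0.25 (detected on 1 of 4 peritoneal arrays). The interferon call ended with a stricter filter on dim probes (adjusted p = 0.38) and without PtC+ peritoneum replicate 1 (adjusted p = 0.054).

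Other lists held called members without passing camera between spleen and peritoneum. Stress and dissociation genes, which share Egr1, Fos, Jun and Atf3 with the lists above, rose in 9 of 21 and fell in 2 (adjusted p = 0.069 preset), and Jun, detected on 2 of 4 peritoneal arrays, rose by 3.72 ± 0.32. NF-kB targets rose in 6 of 23 and fell in 1 (7 and 1 when adjusted over the list alone, adjusted p = 0.051), led by Nfkbiz at 2.51 ± 0.19 (detected on 3 of 4 peritoneal arrays). B cell receptor components rose in 11 of 29 and fell in 2 (11 and 3 when adjusted over the list alone, adjusted p = 0.24). By limma 3516 genes passed, 2051 higher and 1465 lower in spleen, of which 907 and 464 differed at least 2-fold. The count became 1906 without PtC+ spleen replicate 1, 2250 without PtC+ spleen replicate 2, 1882 and 1832 without PtC- spleen replicates 1 and 2, 2061 without PtC+ peritoneum replicate 2 and 5954 without PtC- peritoneum replicate 1. Median centring moved the median of all genes by 0.24 log2 units and split its 3039 calls into 2689 higher and 350 lower.

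TCL1-192 peritoneal cells were compared with wild type peritoneal cells, 4 arrays against 2. The labels call the cells of both groups CLL cells, and Xist and Eif2s3y also differ between them, so whether wild type cells are the normal counterpart is left open. Proliferation genes were higher almost throughout: 33 of 34 rose and 0 fell, also when adjusted over the list alone, with a median of 2.46 (camera adjusted p = 7.4e-23 preset, adjusted p = 0.21 with an estimated correlation). Birc5, or survivin, which acts in mitosis and in survival, rose 22.8-fold (4.51 ± 0.23, SE, limma adjusted p = 1.9e-05). The mitotic kinase gene Pbk rose 22.3-fold, and Nusap1, a spindle protein gene, rose by 3.89 ± 0.18. Outside the lists, Neto2 rose at least 38.4-fold, the matrix protein gene Sparc 62.3-fold, the ETS factor gene Etv5 32.2-fold and Vpreb3, a gene of early B cells, 25.9-fold. The hemoglobin genes Hbb-b1 and Hba-a1 rose 200-fold and 146-fold. Pbk, Sparc, Etv5, Vpreb3 and Hba-a1 were detected on 1 of the 2 wild type arrays, so their folds rest in part on undetected values. Erythroid markers rose in 4 of 8 (5 when adjusted over the list alone), with a median of 1.08, or 0.63 at the detection limit. That list passed camera at adjusted p = 0.00029 preset, with adjusted p = 0.19 with an estimated correlation.

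Immunoglobulin genes went the other way in TCL1-192 cells: 39 of 52 fell and 4 rose (40 and 5 when adjusted over the list alone). Their median was -2.06, or -1.19 with undetected values set to the detection limit (camera adjusted p = 3e-18 preset, adjusted p = 0.051 with an estimated correlation). The kappa variable gene IGKV4-91 lay at 14.89 and 11.57 on the wild type PtC+ and PtC- arrays and at no more than 4.91 on any TCL1-192 array, a fall of at least 165-fold (limma adjusted p = 1.6e-06). Igk-V5 (detected on 1 of the 4 peritoneal TCL1-192 arrays) fell 165-fold, IGKV8-31 at least 39.1-fold and IGKV3-2 at least 37-fold. The 4 that rose were the heavy chain genes Igh-VS107 (3.99 log2 units), Igh-V11 (1.08) and IGHV12S1 (0.84) and the kappa gene IGKV9-128 (1.09). IGKV9-128 lay at 15.04 to 15.35 on TCL1-192 arrays, near the array ceiling of 15.48, so its size is uncertain. Igh-V11 averaged 14.12 in PtC+ and 14.8 in PtC- TCL1-192 cells over both tissues, so the size of its rise is uncertain as well. For IGHV12S1 PtC+ minus PtC- was 1.67 in wild type and -0.65 in TCL1-192 peritoneum, so its rise came from PtC- cells. Among PtC+ cells IGHV12S1 averaged lower in TCL1-192 than in wild type. VH11 and VH12 heavy chains are known from PtC-binding B-1 receptors. A filter asking for detection on 6 arrays, which by its construction drops genes silent in TCL1-192 cells, left the list at a median of 0 (adjusted p = 0.48).

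**Figure D2:**
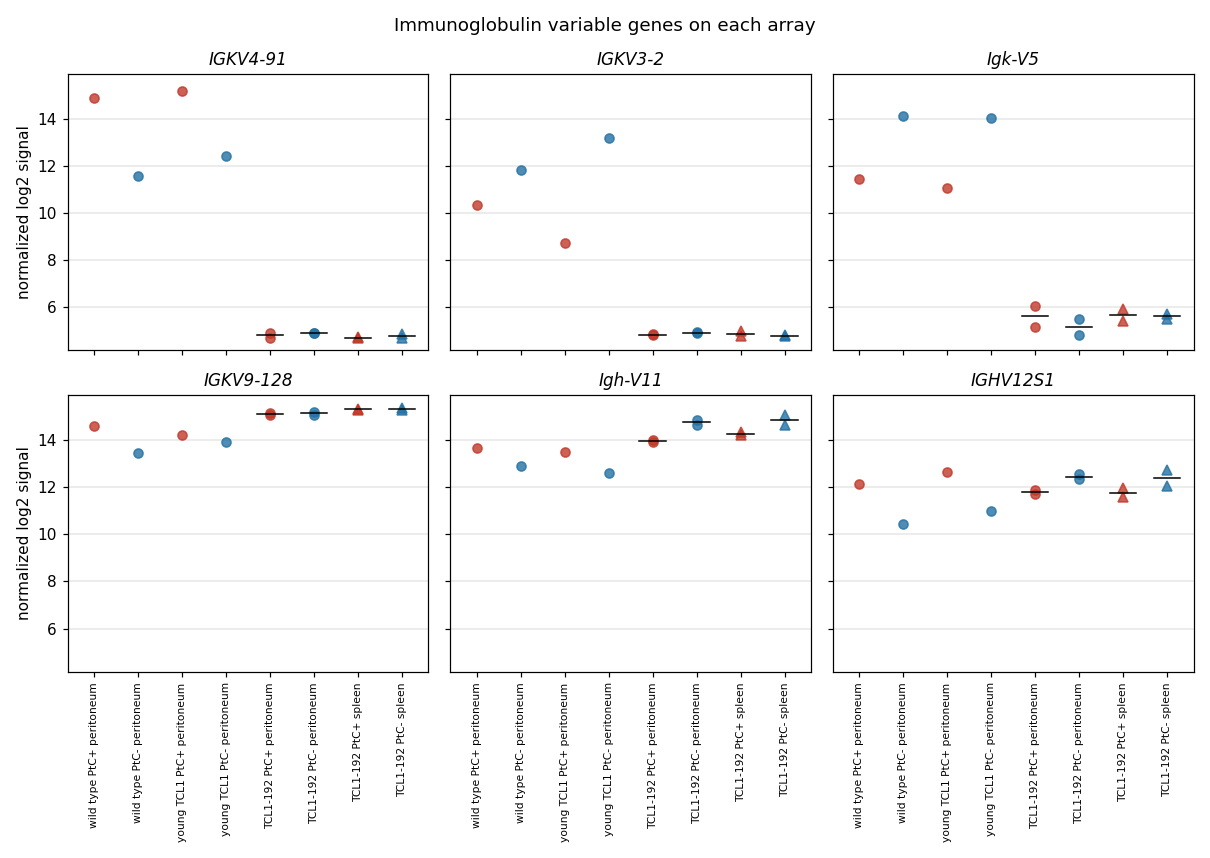
Normalized log2 signal of 6 immunoglobulin variable genes, 1 point per array (red PtC+, blue PtC-, circles peritoneum, triangles spleen, bars the mean of 2 arrays). IGKV4-91, IGKV3-2 and Igk-V5 lie near the detection limit on all 8 TCL1-192 arrays, while IGKV9-128, Igh-V11 and IGHV12S1 are detected on all 12.

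Among the largest falls in TCL1-192 against wild type cells was Ly6a. It encodes the surface protein Sca-1, was undetected on the 4 TCL1-192 arrays and fell at least 389-fold (limma adjusted p = 1.7e-06). Serpina3g fell at least 85.1-fold and Pafah1b3, a subunit of platelet-activating factor acetylhydrolase, at least 123-fold. Homing receptors and adhesion genes fell in 9 of 26 and rose in 0 (10 and 0 when adjusted over the list alone, median -0.52, or -0.4 at the limit, camera adjusted p = 0.00017 preset, adjusted p = 0.19 with an estimated correlation), including Ccr6 at -2.82 ± 0.32 (detected on 1 of 4 TCL1-192 arrays). Follicular and marginal zone markers fell in 7 of 18 and rose in 0 (8 and 0 when adjusted over the list alone, median -0.69, adjusted p = 0.00017 preset, adjusted p = 0.19 with an estimated correlation), including Klf2 at -1.47 ± 0.16. B-1 markers fell in 11 of 22 and rose in 1 (13 and 1 when adjusted over the list alone, median -0.78, or -0.75 at the limit, adjusted p = 0.00021 preset, adjusted p = 0.34 with an estimated correlation). Ctla4, detected on 3 of 4 TCL1-192 arrays, changed by -3.49 ± 0.24 and Anxa2, an annexin, by -2.79 ± 0.17. NF-kB targets fell in 9 of 23 and rose in 1, also when adjusted over the list alone (median -0.58, or -0.54 at the limit, adjusted p = 0.0077 preset, adjusted p = 0.19 with an estimated correlation), with the lymphotoxin gene Ltb at -3.43 ± 0.3.

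Activation, stress and receptor component lists were also lower in TCL1-192 than in wild type cells. Activation genes fell in 10 of 25 and rose in 2 (12 and 3 when adjusted over the list alone, median -0.65, camera adjusted p = 0.026 preset, adjusted p = 0.4 with an estimated correlation). Egr1 changed by -2.42 ± 0.26, while Dusp6, a phosphatase that restrains ERK, rose by 2.57 ± 0.18. The activation call ended without wild type PtC- (adjusted p = 0.081), without PtC+ peritoneum replicate 1 (0.052) and with all probes tested (0.41). Stress and dissociation genes fell in 7 of 21 and rose in 2 (9 and 3 when adjusted over the list alone, median -0.48, adjusted p = 0.019 preset, adjusted p = 0.19 with an estimated correlation), a call that ended without wild type PtC- (adjusted p = 0.059) and with median centring (0.064). Hspb1, a small heat-shock protein gene detected on 1 of 2 wild type arrays, rose by 4.44 ± 0.34 against that direction. B cell receptor components fell in 9 of 29 and rose in 2 (11 and 3 when adjusted over the list alone, median -0.26, adjusted p = 0.024 preset, adjusted p = 0.4 with an estimated correlation, and 0.051 with median centring). Among receptor inhibitors Cd72 rose by 3.83 ± 0.19 and Fcgr2b by 1.7 ± 0.19. MYC targets rose in 7 of 27 (6 when adjusted over the list alone, median 0.37, adjusted p = 0.0054 preset, adjusted p = 0.4 with an estimated correlation, and 0.08 with median centring). Oxidative phosphorylation genes rose in 7 of 28, also when adjusted over the list alone (median 0.42, adjusted p = 0.00024 preset, adjusted p = 0.34 with an estimated correlation), led by Ndufb9 at 2.04 ± 0.26.

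Markers of other peritoneal cell types shifted beside these groups in TCL1-192 cells. Mast cell markers fell in 4 of 5 (5 when adjusted over the list alone), with a median of -3.8, or -2.77 at the detection limit (camera adjusted p = 8e-06 preset, adjusted p = 0.1 with an estimated correlation), and the mast cell protease gene Cpa3 fell at least 16-fold. Macrophage markers fell in 11 of 19 and rose in 2, also when adjusted over the list alone (median -1.22, adjusted p = 0.0015 preset, adjusted p = 0.37 with an estimated correlation, and 0.095 with a stricter filter on dim probes). Fn1, or fibronectin, changed by -4.37 ± 0.28 and Gata6, the factor of resident peritoneal macrophages, fell at least 3.74-fold, while Apoe rose by 2.51 ± 0.18. The Y-linked gene Eif2s3y was undetected on the 4 TCL1-192 arrays and fell at least 25.6-fold. By limma 3613 genes passed, 1561 higher and 2052 lower in TCL1-192 cells. The count became 1239 without wild type PtC+, 2217 without wild type PtC-, 6053 without PtC- peritoneum replicate 1, and 1297 in a fit of the compared arrays only. Median centring moved the median of all genes by -0.231 and split its 2808 calls into 499 higher and 2309 lower.

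**Figure D3:**
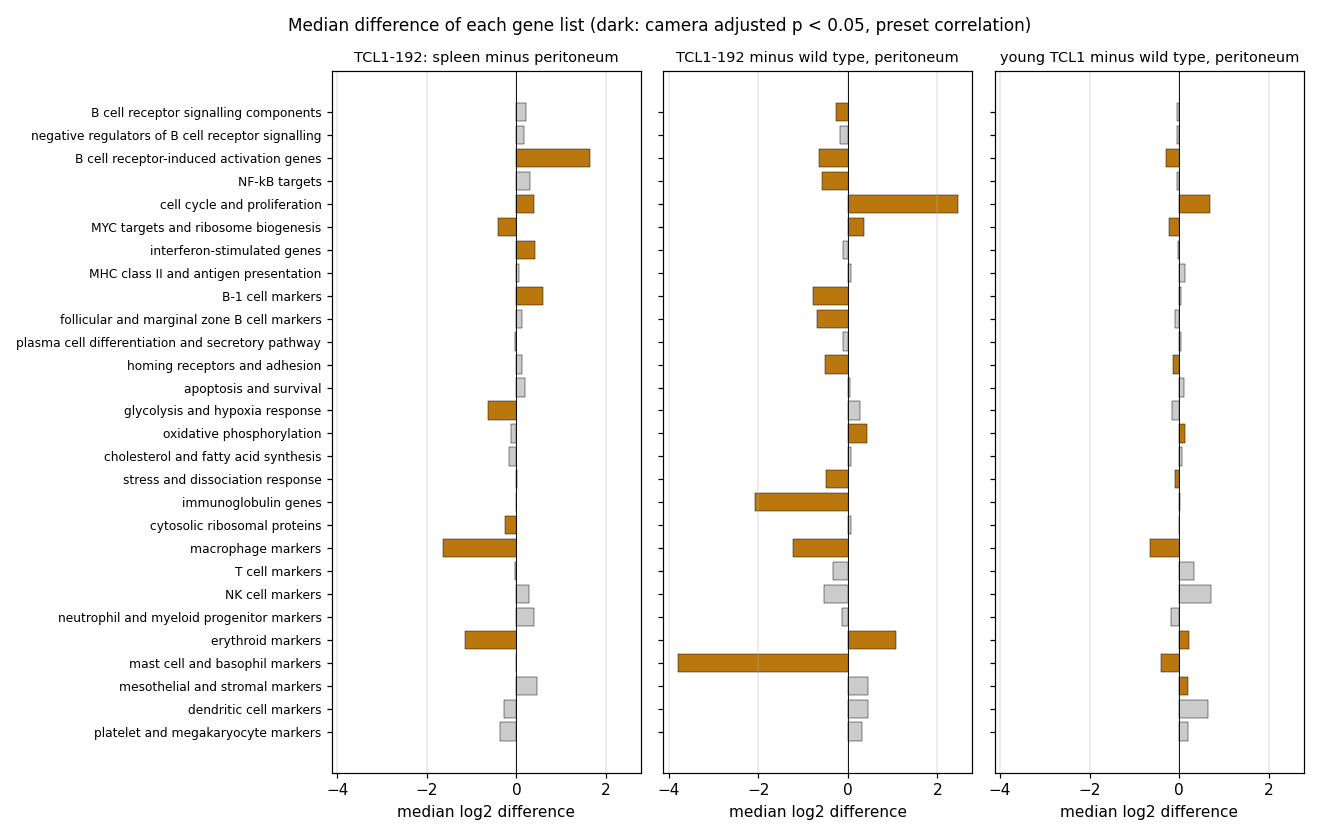
Median log2 difference of each of the 28 fixed gene lists in 3 comparisons. Dark bars passed camera at adjusted p under 0.05 with the preset correlation, and no list in these panels passed with an estimated correlation. Cell cycle genes have medians of 0.4, 2.46 and 0.68 from left to right.

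Young TCL1 cells were set against wild type cells to look for changes present early, with 2 arrays against 2 and no replicates. Ly6a was the furthest apart, at 14.46 and 14.47 on the wild type arrays and undetected in young TCL1 cells, a fall of at least 502-fold (limma adjusted p = 2.1e-05). H2-Ea, an MHC class II alpha chain gene, fell at least 170-fold, Slpi, a secreted protease inhibitor gene detected on 1 of 2 young TCL1 arrays, 240-fold, and Fcer1g, the Fc receptor gamma chain gene, at least 13.7-fold. Ybx3, a cold-shock domain protein gene, fell 17.8-fold and Gprc5b, detected on 1 of 2 young TCL1 arrays, 11.9-fold. Among rises, Neto2 rose at least 15.6-fold (4.85 ± 0.21, SE, adjusted p = 0.00018). Cd27, a receptor of the TNF receptor family on memory and B-1 cells and detected on 1 of 2 wild type arrays, rose 10.7-fold, Camk2n1, an inhibitor of CaM kinase II, 5.55-fold and Krt8 5.19-fold. Hbb-b1 rose 7.73-fold (adjusted p = 0.0052, and 0.11 without either PtC- array). H2-Ea was at 8.21 to 10.63 on the peritoneal and at 5.33 to 6.2 on the spleen TCL1-192 arrays.

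Cell cycle genes had a median of 0.68 in young TCL1 against wild type cells, or 0.64 at the detection limit, with 1 of 34 rising over all genes and 11 when adjusted over the list alone (camera adjusted p = 6.5e-13 preset, adjusted p = 0.46 with an estimated correlation). Without the wild type or the young PtC+ array, which leaves the PtC- comparison alone, the median turned to -0.11. Macrophage markers fell in 4 of 19 (9, with 1 rising, when adjusted over the list alone), with a median of -0.65 (adjusted p = 3.2e-07 preset, adjusted p = 0.41 with an estimated correlation). That median turned to 0.04 without the wild type or the young PtC- array, which leaves the PtC+ comparison alone. Of the other lists past the preset test, MYC targets had a median of -0.22 (adjusted p = 0.008) and mast cell markers -0.41 (0.008). Erythroid markers had a median of 0.21, or 0.09 at the limit (adjusted p = 0.023), and activation genes -0.3, or -0.27 at the limit (0.025). Homing receptors had a median of -0.14 (adjusted p = 0.028), and mesothelial and stromal markers 0.2, or 0 at the limit (0.028). Oxidative phosphorylation genes had a median of 0.13 (adjusted p = 0.038), and stress and dissociation genes -0.1, or -0.09 at the limit (0.043). With an estimated correlation the adjusted p of these 8 lists was 0.41 to 0.6. Over all genes 3 activation genes, 2 homing receptors, 2 stress genes and 1 mast cell gene fell, and 2 erythroid genes and 1 stromal gene rose. When adjusted over the list alone these were 5, 5, 5 and 2 falling and 2 and 2 rising, with 1 activation and 1 stress gene rising.

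Each of those 8 calls in young TCL1 cells ended when 1 array, and with it the comparison within its PtC class, was left out. Leaving out the wild type or the young array of a class left the same contrast, the other class alone. Without the PtC- array of wild type or of young TCL1, MYC targets (-0.16, adjusted p = 0.12), mast cell markers (-0.39, 0.13), homing receptors (-0.08, 0.27), oxidative phosphorylation (-0.05, 0.76 or 0.75) and erythroid markers (-0.01, 0.15 or 0.16) no longer passed. The activation list ended without either PtC+ array (-0.29, adjusted p = 0.059) and without either PtC- array (-0.26, 0.12). Stress genes ended without either PtC+ array (-0.34, adjusted p = 0.062) and without either PtC- array (-0.15, 0.15 or 0.16), as did mesothelial and stromal markers (0.31, 0.062, and 0.11, 0.1). Alternative settings also ended the calls of MYC targets (adjusted p = 0.053 with median centring), oxidative phosphorylation (0.084 with median centring, 0.06 with a stricter filter), homing receptors (0.063 with a stricter filter) and stress genes (0.11 with all probes tested). By limma 201 genes passed, 80 higher and 121 lower in young TCL1 cells. The count became 57 without either PtC- array and 116 without either PtC+ array. It was 408 with quantile normalization alone, 381 with the deposited normalized values, 355 with an intensity trend, 125 with median centring, 110 (59 higher, 51 lower) with a stricter filter on dim probes, 89 with the source pair as a random block and 368 with array quality weights.

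TCL1-192 peritoneal cells were also compared with young TCL1 cells, 4 arrays against 2, and the 2 groups also differ in Xist and Eif2s3y. Spred1, an inhibitor of RAS signalling detected on 1 of 2 young TCL1 arrays, rose 23.4-fold (4.55 ± 0.15, SE) and Cd72, an inhibitory coreceptor gene, 21-fold (4.39 ± 0.19), while Etv5 rose at least 28.1-fold. Birc5 was higher by 3.33 ± 0.23, and cell cycle genes rose in 28 of 34 and fell in 0 (31 and 0 when adjusted over the list alone, median 1.77, camera adjusted p = 2.4e-21 preset, adjusted p = 0.21 with an estimated correlation). Immunoglobulin genes fell in 39 of 52 and rose in 3 (40 and 4 when adjusted over the list alone), IGKV4-91 at least 244-fold and Igk-V5 (detected on 1 of 4 TCL1-192 arrays) 141-fold. Their median was -2.11, or -1.13 at the detection limit, and the list passed with the preset correlation (adjusted p = 2.6e-21) and at adjusted p = 0.037 with an estimated correlation, but had a median of 0 with the stricter filter (adjusted p = 0.39). Ctla4 changed by -4.52 ± 0.24. B-1 markers fell in 10 of 22 (16 when adjusted over the list alone, median -0.8, adjusted p = 4.1e-06 preset, adjusted p = 0.21 with an estimated correlation). NF-kB targets fell in 10 of 23 (11 when adjusted over the list alone, median -0.87, or -0.72 at the limit, adjusted p = 0.00032 preset, adjusted p = 0.18 with an estimated correlation). MYC targets rose in 11 of 27 (12 when adjusted over the list alone, median 0.6, adjusted p = 2.4e-06 preset, adjusted p = 0.21 with an estimated correlation). Mast cell markers fell in 4 of 5, also when adjusted over the list alone (median -3.52, or -2.49 at the limit, adjusted p = 4.1e-06 preset, adjusted p = 0.1 with an estimated correlation) and erythroid markers rose in 4 of 8, likewise (median 0.96, or 0.55 at the limit, adjusted p = 0.001 preset, adjusted p = 0.21 with an estimated correlation).

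Further lists between TCL1-192 and young TCL1 cells passed the preset test but not every array left out. Follicular markers (median -0.86, or -0.65 at the limit, adjusted p = 0.00026) and homing receptors (-0.44, or -0.21 at the limit, 0.0044) ended without young PtC+ (adjusted p = 0.057 and 0.19). Glycolysis genes (0.47, 0.0037) ended without PtC- peritoneum replicate 1 (0.068) and without young PtC- (0.19). Oxidative phosphorylation genes (0.18, adjusted p = 0.0084) ended without young PtC+ (0.59) and without PtC- peritoneum replicate 2 (0.052). Receptor components (-0.41, adjusted p = 0.018) ended without young PtC+ (0.43) and without PtC+ peritoneum replicate 2 (0.053). With an estimated correlation the adjusted p of these 5 lists was 0.21 or 0.4. In that order 7, 8, 8, 5 and 10 of their members passed in the direction of the median, and 11, 9, 8, 5 and 11 when adjusted over the list alone. T cell markers (median -0.82, or 0 at the limit, adjusted p = 0.045 preset, adjusted p = 0.21 with an estimated correlation) turned to 0.08 without young PtC- (adjusted p = 0.94) and to 0.63 with the stricter filter (0.23). They also ended without PtC- peritoneum replicate 1 (adjusted p = 0.09), without PtC+ peritoneum replicate 2 (0.053), with an intensity trend (0.066) and with quantile normalization alone (0.051). NK cell markers (-1.31, or -0.51 at the limit, adjusted p = 0.045 preset, adjusted p = 0.21 with an estimated correlation) ended without PtC+ peritoneum replicate 1 (0.064), PtC- peritoneum replicate 1 (0.13), PtC+ peritoneum replicate 2 (0.057) or young PtC- (0.94), with the stricter filter (0.3) and with an intensity trend (0.054). By limma 2594 genes passed, 1047 higher and 1547 lower, against 1478 without young PtC+, 1626 without PtC+ peritoneum replicate 2, 5330 without PtC- peritoneum replicate 1 and 745 in a fit of the compared arrays only. Median centring moved the median of all genes by -0.254 and split its 2228 calls into 346 higher and 1882 lower.

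Over all 6 sources, 6 PtC+ arrays against 6 PtC- arrays, the immunoglobulin genes were the group furthest apart. Of 52, 24 fell in PtC+ cells and 1 rose (38 and 3 when adjusted over the list alone), with a median of -0.83, or -0.68 at the detection limit. The list passed camera at adjusted p = 3.7e-51 preset and at adjusted p = 0.0065 with an estimated correlation, but not with a stricter filter on dim probes (median -0.01, adjusted p = 0.52). The heavy chain gene IGHV1S119 changed by -2.02 ± 0.12 (SE, limma adjusted p = 0.00067), and in wild type cells it was at 6.61 on the PtC+ and 11.11 on the PtC- array. Both falls came from the wild type and young TCL1 pairs, 1 pair each, with list medians of -1.3 and -2.05. In TCL1-192 cells the list median was -0.01 in peritoneum, where 37 of the 52 genes were detected on no array, and 0 in spleen. IGHV1S119 was undetected in both tissues and differed by 0.09 and 0.06. Its SE thus rests on values near the detection limit and on the prior, with no replicates of the pairs that fell. Cell cycle genes rose in 8 of 34 (22 when adjusted over the list alone), with a median of 0.63 (adjusted p = 5.3e-30 preset, adjusted p = 0.29 with an estimated correlation). Nusap1 rose 2.48-fold (1.31 ± 0.13, adjusted p = 0.0051), but by 0.48 without the young PtC+ or PtC- array (adjusted p = 0.46). Without either young array the cell cycle median was 0.25 and 1 gene of all tested was called higher. By source that median was 1.43 in young TCL1 and 0.13 in wild type cells, and 0.14 and 0.4 in TCL1-192 peritoneum and spleen. By limma 106 genes passed, 23 higher and 83 lower, and 0 with the source pair as a fixed block. The count was 3 (2 higher, 1 lower) with the stricter filter, 36 (1 higher, 35 lower) without young PtC+, 37 (1 higher, 36 lower) without young PtC- and 525 (224 higher, 301 lower) without PtC- peritoneum replicate 1. It was 60 without either wild type array, 68 and 65 without PtC+ peritoneum replicates 1 and 2, 63 without either PtC+ spleen array, and 59 and 64 without PtC- spleen replicates 1 and 2. Median centring moved the median of all genes by 0.116.

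T cell markers had a median of -0.34 over all 6 sources, with 1 falling and 4 when adjusted over the list alone (camera adjusted p = 0.00012 preset, adjusted p = 0.14 with an estimated correlation) and -0.01 without either young array (adjusted p = 0.97). NK cell markers had a median of -0.31, or 0 at the limit (adjusted p = 0.0056 preset, adjusted p = 0.27 with an estimated correlation), against -0.04 without either young array (0.74) and 0.08 with the stricter filter (0.9). Macrophage markers had a median of 0.22, with 0 past and 2 higher when adjusted over the list alone (adjusted p = 0.0043 preset, adjusted p = 0.7 with an estimated correlation), which turned to -0.14 without either young array (0.019) and ended with the stricter filter (0.14). B cell receptor components (median -0.1, adjusted p = 0.011 preset), negative receptor regulators (-0.1, 0.017), MYC targets (0.11, 0.023) and mast cell markers (-0.2, 0.031) had an adjusted p of 0.33 to 0.76 with an estimated correlation. Each of these 4 calls ended without PtC- peritoneum replicate 1 (adjusted p = 0.12, 0.47, 0.23 and 0.12 in that order). Receptor components also ended without either wild type array (adjusted p = 0.12) or PtC+ peritoneum replicate 2 (0.062) and with median centring (0.67), and negative regulators without wild type PtC+ (0.1) or PtC- (0.11), young PtC+ (0.07) or PtC- (0.069) and with median centring (0.32). MYC targets also ended without either young array (adjusted p = 0.17), PtC+ spleen replicate 1 (0.14) or PtC- spleen replicate 2 (0.078). Mast cell markers also ended without either wild type array (adjusted p = 0.66), either young array (0.14), PtC+ or PtC- spleen replicate 1 (0.059 and 0.058) or PtC- peritoneum replicate 2 (0.096), and with an intensity trend (0.13).

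In wild type cells, on 1 array each and with no test, the PtC+ array stood out for the light chain gene IGKV4-91, at 14.89 against 11.57 on the PtC- array. Immunoglobulin genes had a median difference of -1.3, below all 10000 random lists of like signal, and macrophage markers -0.53, also below all of them. In young TCL1 cells the PtC+ array was higher for Nusap1, at 9.64 against 5.85, and for Fn1, at 10.46 against 5.61. Cell cycle genes there had a median of 1.43 and macrophage markers 1.68, both above all random lists, and immunoglobulin genes -2.05, below all of them. The T cell gene Cd3d was at 5.65 on the PtC+ and 9 on the PtC- array, and T cell markers had a median of -1.69. Genes 2-fold apart numbered 358 in wild type cells (168 higher in PtC+, 190 lower) and 1095 in young TCL1 cells (569 higher, 526 lower). The wild type count was 122 with quantile normalization alone, 131 with the deposited values, 173 (107 higher, 66 lower) with the stricter filter and 478 (300 higher, 178 lower) with median centring. The young count was 410 with quantile normalization alone and 445 with the deposited values. The single replicate pairs of TCL1-192 cells gave 116 higher and 91 lower and, with the array of raised background, 1423 higher and 1295 lower in the peritoneum. In the spleen they gave 62 higher and 36 lower, and 25 higher and 49 lower. Of the 10 genes with the highest t for a rise in TCL1-192 PtC+ cells, 4 went the same way in wild type and 6 in young TCL1 cells, and of the 10 for a fall, 7 and 2. Across genes, which are not independent replicates, the PtC differences of wild type and young TCL1 cells had r = 0.16 and rho = -0.029. Against TCL1-192 peritoneum wild type cells had r = 0.18 and rho = 0.22, and young TCL1 cells r = -0.28 and rho = -0.34. The PtC differences of TCL1-192 spleen had r = 0.019 with wild type, -0.0042 with young TCL1 and -0.068 with TCL1-192 peritoneum.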

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

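All tests in this part were chosen after the results were seen, except the counts over other splits of the arrays. The PtC difference of immunoglobulin genes stood out between donors: in the peritoneum it differed between TCL1-192 cells and the mean of wild type and young TCL1 cells for 91 genes by limma (74 higher, 17 lower, 161 in all without PtC- peritoneum replicate 2). Immunoglobulin genes made up 22 of them, 21 higher, with a median of 1.65 over 52 genes (camera adjusted p = 7.4e-22 preset, adjusted p = 0.035 with an estimated correlation). Their median PtC+ minus PtC- difference was -1.3 in wild type and -2.05 in young TCL1 cells, each from 1 pair of arrays, and -0.01 in TCL1-192 cells. All 22 were among the 37 immunoglobulin genes detected on no peritoneal TCL1-192 array, so their difference there could only lie near 0 and these calls restate the wild type and young TCL1 difference. The 9 detected on all 4 arrays had 0 calls and a median of 0 in wild type and young TCL1 cells. Members lay on both sides of it, with Igh-V11 at 0.78 and 0.89 and the lambda constant gene IGLC2 at -0.14 and -0.53. The 6 detected on some arrays had 0 calls, with medians of -0.65 in wild type, -2.06 in young TCL1 and -0.08 in TCL1-192 cells.

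The high immediate-early genes of splenic TCL1-192 cells (Egr1, Fos, Fosb, Atf3) were set against 3 technical explanations. A raised background on 1 peritoneal array is not the whole cause, since without that array the activation list still had a median of 1.69. Fewer B cells in the peritoneal samples would raise genes confined to B cells in spleen. B cell receptor components had a median of 0.21, with quartiles of -0.24 and 0.64, although macrophage markers such as Lyz2 fell. These components include genes such as Syk and Ptprc that are not confined to B cells. The list therefore cannot exclude a part played by fewer B cells. Stress of cell preparation in the spleen stays open, since heat-shock genes had a median of -0.14 with members on both sides (Hspa1a at 1.2 and Hspe1 at -1.12, 9 of 11 not past the test). Receptor signalling in the spleen is a biological hypothesis that may account for the pattern, and remains untested.

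The loss of immunoglobulin variable genes in TCL1-192 cells was set against less immunoglobulin RNA and against growth of few clones. Less immunoglobulin RNA overall is not the whole cause, since 4 variable genes were called higher while 38 were called lower, Igh-VS107 by 3.99 log2 units and clear of the array ceiling. The constant genes decide nothing, since Igh-6 (-0.32 ± 0.15, limma adjusted p = 0.18) lay at 14.73 to 15.41, near the ceiling of the arrays at 15.48, and Igk-C lay at it on all 12. Of 47 variable genes detected in wild type cells, 33 were detected on no TCL1-192 array, a pattern consistent with growth of few clones, as a hypothesis found in these same data. The constant genes were examined first and the variable genes after them.

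Ly6a, H2-Ea and other extreme differences between TCL1-bearing and wild type cells were set against sex and strain of the donors. Xist was at 8.07 to 10.48 on TCL1-192 arrays and at 4.91 to 5.12 on the others, and Eif2s3y at 4.68 to 4.79 against 10.27 to 11.19. Of the genes called between TCL1-192 and wild type, 2357 had a chromosome in the array annotation, and 2.76% of these lay on X or Y. Among all tested genes with a chromosome the share was 3.33%. Sex can also act on genes elsewhere, so this share cannot exclude it for that comparison. Young TCL1 and wild type arrays shared low Xist and high Eif2s3y. This argues against sex for differences between those 2 groups, Ly6a and H2-Ea included. Genes called between young TCL1 and wild type lay near one another in 18 pairs, against a median of 5 and at most 11 in 1000 random draws (one-sided permutation p = 0.001, the smallest these draws can give), while as many spleen against peritoneum genes gave 7 pairs. Of the 18 pairs 10 held a member of a fixed list or of a family such as histones, mast cell proteases or MHC genes, which other causes can move together, and without such genes there were 8 pairs against a median of 2 and at most 9 in 1000 random draws (one-sided permutation p = 0.007). This may reflect blocks of strain variants, since C57BL/6 mice do not express H2-Ea and C3H mice express little Ly6a. The labels, though, give all samples 1 mixed C3H/C57BL/6 background, and the 2 genes, both low in young TCL1 cells, point to different strains. H2-Ea was also lower on spleen than on peritoneal TCL1-192 arrays, which a strain difference between donor groups would not explain. The TCL1 genotype and age stay open, untested. The first count was run in 3 versions that placed different numbers of genes, each at permutation p = 0.001.

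Other splits of the arrays showed how far chance can be excluded. For spleen against peritoneum 1 of 35 splits of the 8 TCL1-192 arrays, the real one, gave as many genes. It gave 3097 in a fit of these arrays, and any other gave at most 0. These splits take the 8 arrays as independent, although a PtC+ and a PtC- array may share an animal, which is not given. If they do, 35 overstates the number of independent splits and the count cannot exclude chance. For PtC in TCL1-192 cells 12 of 35 splits gave as many genes at an unadjusted p under 0.05 as the real 705, so chance was not excluded. The highest, 4804, was the split by tissue, the only one fitted without tissue as a term. Counted after these results, 11 of the 34 splits fitted with that term gave as many, and the highest other gave 1801. Of the 18 balanced by tissue 6 gave as many and the highest other gave 1185. Over all 6 sources, in a fit with source as a term, the real count was 0 and the highest 333, so the 100 of 100 splits with at least 0 genes were fixed in advance and test nothing.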

How the results depend on the processing

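In this part the array quality weights were chosen after seeing the data; all other alternatives were fixed before. Each named gene result was compared once per alternative. Of these comparisons 6436 counted as unchanged, 622 lost their call, 43 gained one and 1 reversed. Direction was checked only for results past the test, so the unchanged ones may include others that changed sign. Of 363 named gene results past the test, 125 lost the call in at least 1 setting other than leaving out an array. Of the list comparisons 800 kept direction and call, 155 lost the call and 14 reversed. Counts of genes or of list calls stayed within 1.5 times in 169 cases and moved further in 51.

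Young TCL1 against wild type (201 genes) gave 408 with quantile normalization alone, 125 with median centring, 381 with the deposited values, 110 with the stricter filter, 355 with an intensity trend, 89 with the source pair as a random block and 368 with array quality weights. Genes 2-fold apart in the wild type pair went from 358 to 122 with quantile normalization alone, 131 with the deposited values and 173 with the stricter filter, and in the young pair from 1095 to 410 and 445 with the first 2. PtC over all 6 sources gave 3 genes with the stricter filter and 0 with the source pair as a fixed block, and peritoneal PtC gave 143 with an intensity trend. Fits of the compared arrays only, with fewer arrays behind the spread, gave 1297 genes for TCL1-192 against wild type and 745 against young TCL1. A 2-fold minimum by its construction lowered spleen against peritoneum to 1371, TCL1-192 against wild type to 2045 and against young TCL1 to 1502. With an estimated correlation 2 of 61 list calls passed. Apart from the 2-fold minimum and the smaller fits, the cause was not tested.

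Lists that reversed were MHC class II for PtC in TCL1-192 cells (0.22 with median centring), T cell markers against young TCL1 (0.63 with the stricter filter) and NK cell markers over all sources (0.08 with it). Immunoglobulin genes of TCL1-192 against wild type and against young TCL1 were at 0 with that filter, which drops genes detected on few arrays. Without 1 array, young TCL1 against wild type gave -0.11 to 1.37 for cell cycle genes, -0.05 to 0.45 for oxidative phosphorylation and -1.87 to 0.04 for macrophage markers. Over all sources macrophage markers gave -0.14 to 0.47. TCL1-192 against young TCL1 gave -1.37 to 0.08 for T cell markers and -2.93 to 0.32 for the NK cell gene Nkg7.

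Leaving out 1 array in turn gave 1832 to 5954 genes for spleen against peritoneum, 1239 to 6053 for TCL1-192 against wild type, 57 to 116 for young TCL1 against wild type, 1478 to 5330 for TCL1-192 against young TCL1 and 36 to 525 for PtC over all sources. PtC in TCL1-192 cells gave 0 to 1528, in the peritoneum 0 to 2752, and its difference between tissues 0 to 1644. The highest of each but young TCL1 came without PtC- peritoneum replicate 1. Without the array of raised background itself (PtC- peritoneum replicate 2) these were 3873, 4205, 3143 and 145, with 0 for the 3 PtC tests.

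With the replicate number as a block, limma gave 2259 higher and 1625 lower genes for spleen against peritoneum, and 0 for the PtC tests in TCL1-192 cells, with 63 list calls. The block ended no comparison's count and moved none beyond 1.5 times. As a check of pairing, deviations of replicate 1 from its group mean correlated across genes at r = 0.054 to 0.26 between groups, which does not establish that replicate numbers pair the arrays. A block for array chips was not run, as the files give no chip. Young TCL1 against wild type was not fitted with its own arrays only, where 1 mean per group leaves 0 residual degrees of freedom. A fit of those arrays with fewer terms was not run either. The lone arrays, and the raised background of 1 array, limit how small a difference could be detected.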

Other observations

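Secretory pathway genes moved in both directions between splenic and peritoneal TCL1-192 cells, 4 of 24 rising and 5 falling (median -0.03, camera adjusted p = 0.64 preset). Fkbp11, a folding factor of secretory cells, fell 16.9-fold in spleen (-4.08 ± 0.15, SE, limma adjusted p = 2.1e-05) and the chaperone gene Calr by 3.45-fold, while Atf4, a factor of the integrated stress response, rose by 1.51 ± 0.15. Of 26 apoptosis and survival genes 4 rose and 3 fell (median 0.19, or 0.16 at the detection limit, adjusted p = 0.46). Cdkn1a, the p53 target p21, detected on 3 of 4 peritoneal arrays, rose by 1.98 ± 0.29 and Tnfrsf13c, the BAFF receptor gene, by 0.95 ± 0.14. Among negative receptor regulators Pecam1 (detected on 3 of 4 peritoneal arrays) rose by 1.72 ± 0.18 and Siglecg by 1.24 ± 0.16 (list median 0.16, or 0.05 at the limit, adjusted p = 0.66). In MHC genes the peptide transporter genes Tap1 and Tap2 rose by 1.02 ± 0.17 and 1.02 ± 0.12 (list adjusted p = 0.7). Cholesterol and fatty acid genes rose in 2 of 20 and fell in 4 (median -0.17, or -0.06 at the limit, adjusted p = 0.5).

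Smaller cell type lists did not pass camera between the tissues. The calprotectin gene S100a8 rose at least 2.16-fold in spleen (neutrophil and myeloid progenitor list, adjusted p = 0.4), and the keratin gene Krt8 by 2.77 ± 0.12 while the stromal gene Dcn fell at least 5-fold (mesothelial and stromal list, adjusted p = 0.22). Cxcl4, now Pf4, fell at least 4.56-fold (platelet list, adjusted p = 0.16) and Batf3 (detected on 1 of 4 peritoneal arrays) rose by 1.4 ± 0.18 (dendritic cell list, adjusted p = 0.91). Against wild type, TCL1-192 cells held less of the T cell receptor genes Cd3g (-3.79 ± 0.37, detected on 2 of 4 TCL1-192 arrays) and Cd3e (at least 2.58-fold lower) but more of Cd8b1 (2.16 ± 0.27, detected on 1 of 2 wild type arrays), with T cell markers at adjusted p = 0.26. The sterol gene Sqle rose by 1.72 ± 0.15 there (cholesterol list, adjusted p = 0.2), and the survival gene Mcl1 changed by -1.08 ± 0.15 (apoptosis list, adjusted p = 0.82). In both comparisons other peritoneal cell types shifted as well, macrophage markers by medians of -1.64 and -1.22.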
